A study of Danio rerio with 2 samples.

How the data were processed

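RNA sequencing was done on the adult zebrafish forebrain choroid plexus, the folded secretory epithelium and its underlying stroma at the roof of the forebrain ventricle. Per the labels, 2 libraries of total RNA were made from separate pools of 12 to 19 dissected tissues each, taken from untreated fish 6 to 8 months old and over 3 cm long. The fish were of the AB strain and of the nacre line, which lacks functional mitfa and its melanophores. Per the labels, the pineal gland was dissected away before collection. RNA was purified either with glycogen or on spin columns. Which fish and which purification went into which library is not given in the sources used here, so neither could be compared. The sample titles call the libraries batch 1 and batch 2, which are replicates 1 and 2 here. The titles do not say what set the batches apart. Every difference between the replicates is also a difference between the batches.

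Per the submitters' processing notes, STAR and RSEM 1.3.3 were used with genome build GRCz11. The version of STAR and the gene annotation are not given in the sources used here. Per the file headers, the authors deposited for each library the expected counts that RSEM estimated per gene, which need not be whole numbers. Per the file headers, the authors also deposited TPM, which divide the counts by effective transcript length and scale them to the same sum in each library. FPKM values were deposited by the authors in the same files and were not used here. The files of the samples held 25432 genes each. A table of the whole series held 21019 of these genes. Its deposited TPM differed from the mean of both libraries by at most 0.005, so it was used for gene names only. The genes left out of that table had a mean TPM of at most 0.005.

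The expected counts summed to 11712489 in replicate 1 and to 13446356 in replicate 2, and 4.52% and 4.20% of the values were not whole. A count of 3 corresponded to 0.256 and 0.223 CPM, the counts scaled to the library total without regard to length. PCR reads carried no known molecular identifiers, so counting intervals cover counting error only. Gene names came from the authors' table for 20973 genes and from a reference table of gene symbols for 3589 genes, and 870 genes had no name. Symbols of the gene lists were matched by name, and then through the synonyms of a RefSeq table of assembly GRCz12tu. No coordinates are given, because no annotation of GRCz11 was used here. Symbols that matched no gene were left out. For list levels, gene entries that share a symbol were summed. Genes close to 0 carried fewer names from the authors, so the shares of detected members may be too high for lists with many unmatched symbols.

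Both libraries formed 1 group and no comparison between groups was possible, so no statistical test was run and no p-value is given. Levels are given as mean TPM ± SD with n = 2, where the SD of 2 values is their difference divided by the square root of 2. A gene was called detected at a TPM of at least 1 in both replicates, moderate at 10 and high at 100. For 31 gene lists, the median log2(TPM + 1) of the matched members was placed among the medians of 10000 random lists of the same size drawn from all genes. Between replicates, the log2 ratio of TPM + 1 was taken as replicate 2 over replicate 1, less the median of the genes with a mean TPM of at least 1. List medians of this ratio were placed among 10000 random lists matched over 20 bins of mean TPM. The top bin is wide, so matching is coarse for the most abundant lists. Where lists were matched on length too, 10 bins of length and only 5 of mean TPM were used. A change of position in that setting can therefore also come from the coarser matching on mean TPM. Lists beyond the 2.5 and 97.5 percentiles were called lower or higher, as a description of these libraries. Single genes were said to differ at a mean TPM of at least 10 and a ratio of at least 4-fold, a rule of size. Ratios on the TPM + 1 scale understate differences of low genes. A pair of duplicate genes, read from symbols ending in a and b within the lists, was called unequal where the ratio was at least 4-fold the same way in both replicates and the higher copy had a mean TPM of at least 10.

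Genes named in the text followed a rule fixed before the data were examined. It took the 20 most abundant genes outside the mitochondrially encoded and ribosomal protein classes with the top 3 of each class, the top 4 members of each list (8 for 5 main lists), a fixed set of marker genes, the 10 largest ratios each way between replicates and the 10 most abundant unequal pairs. Other genes are said to have been chosen after their values were seen. The gene folr1 of the fixed set matched no gene.

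The procedures were tested on simulated data for 25432 genes, with counts drawn from the means and totals of these libraries. Each gene varied on its own with an assumed spread, without a trend by length and without genes that vary together. The calls of unchanged genes and lists therefore do not measure false calls in the real libraries. For genes that differ between replicates, the rule found 2.0% of genes changed 2-fold, 52% of those changed 4-fold, 96% of those changed 8-fold and 92% of those changed 16-fold, with 50 genes at each size, and it called 6 of 7089 unchanged genes. For gene lists between replicates, 0 of 30 unchanged lists were called. A list raised 1.5-fold gave a mean estimate of 1.36-fold over 20 draws, and the pseudocount of 1 alone leaves 1.40-fold of such a change. For gene list levels, 7 of 200 random lists fell outside the central 95%.

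Alternatives covered the detection threshold, CPM in place of TPM, TMM scaling from edgeR 4.0.16 on expected counts rounded to whole numbers, the pseudocount, filters on low values, thinning of the deeper library, the genes of single classes and each replicate left out. A count was taken as kept within 1.5 times its main value and a level within 1 SD. Correlations were held to their 95% interval over genes, and list medians between replicates to the SD of the random medians, since neither has a replicate spread. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 for edgeR.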

Results

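RNA was sequenced from 2 pools of adult zebrafish forebrain choroid plexus, the tissue that lines and secretes into the ventricle. The series title concerns conservation of the tissue and ventricle size, and the libraries describe which genes the unperturbed tissue transcribes. Replicate 1 held 11712489 expected counts over 20041 genes with reads, and replicate 2 held 13446356 over 19619 genes. At a TPM of at least 1, 15348 and 14449 genes were detected in the replicates and 13897 in both. Of these, 6695 genes reached a TPM of 10 and 794 reached 100 in both replicates.

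Across the 21030 genes with a TPM above 0 in either replicate, the levels in the replicates had a Pearson r of 0.957 on the log2(TPM + 1) scale and a Spearman correlation of 0.936. These are correlations across genes, which are not independent replicates. The median absolute log2 ratio was 0.32, and 90.7% of the genes lay within 2-fold. The ratio here includes a median shift of all genes of -0.25 (log2, replicate 2 over replicate 1), which was removed from every ratio between replicates given below.

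**Figure D1:**
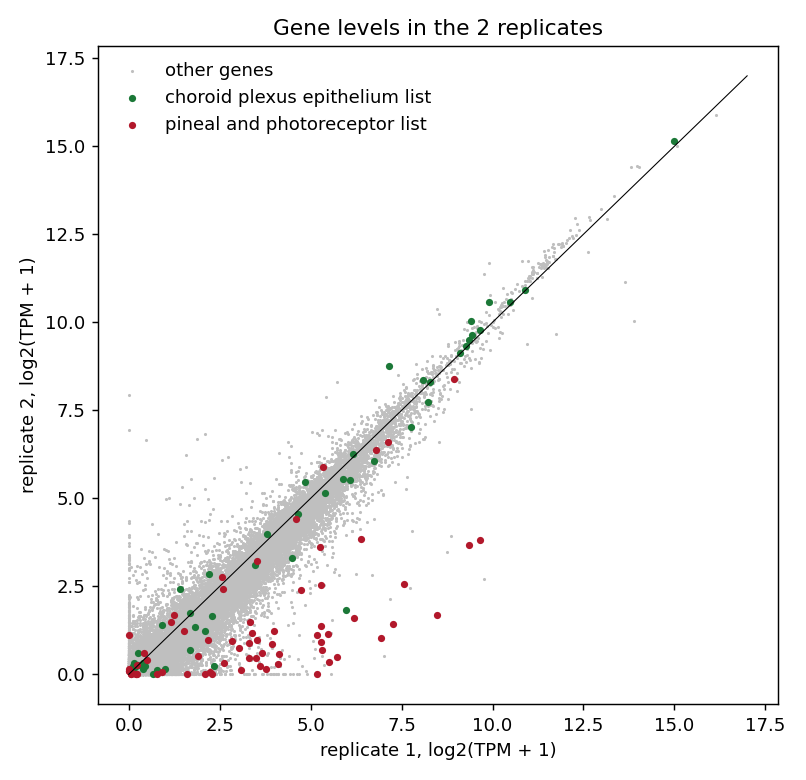
Each point is a gene, with log2(TPM + 1) in replicate 1 on the x axis and in replicate 2 on the y axis, and the line marks equal levels. Most members of the choroid plexus epithelium list (green) lie near the line, though rdh5 lies below it with 61.2 and 2.56 TPM. Many members of the pineal and photoreceptor list (red) lie below the line, as exorh does with 656 and 11.7 TPM.

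A few genes held much of all TPM. The 10 most abundant genes held 23.4 ± 0.103% of all TPM (SD, n = 2), the top 50 held 40.7 ± 1.59% and the top 100 held 53.3 ± 3.00%. The gene zgc:114181 (ENSDARG00000069583) was at 66498 ± 8449.7 TPM, or 6.65 ± 0.845% of the total. It was followed by rbp4, the retinol carrier of plasma, at 34397 ± 2261 TPM, and clu, which encodes the secreted chaperone clusterin, at 33775 ± 1203 TPM. The secreted Wnt modulator family member dkk3b was at 5199 ± 1601 TPM. Genes of translation and the cytoskeleton were also among the top 20, with eef1a1l1 at 11343 ± 1330.2, actb2 at 5400.3 ± 1347, eef2b at 3316 ± 789.7 and vim at 2794 ± 304 TPM. The brain fatty acid binding protein gene fabp7b was at 2628 ± 1154 TPM. Other genes of the top 20 were si:ch211-80h18.1 (8455 ± 934), si:dkey-151g10.6 (7088 ± 822), slc25a5 (5066 ± 494), tpt1 (2965 ± 328), ppiaa (2553 ± 455), nme2b.1 (2538 ± 239), hsp90ab1 (2405 ± 324) and pabpc1a (2403 ± 49.9). For zgc:158463 and FO704772.3 the mean says little, as they stood at 15283 and 1053 TPM and at 12684 and 2268 TPM in replicates 1 and 2. With CPM in place of TPM, 13 of the 20 genes stayed in the top 20.

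The 13 mitochondrially encoded genes took 9.58 ± 2.2% of all TPM, led by mt-co2 (19251 ± 3437), mt-co1 (19219.9 ± 4546) and mt-co3 (18027 ± 5063). Ribosomal protein genes took 22.1 ± 2.71%, led by rps2 (8852 ± 975), rps29 (5792 ± 681) and rpl34 (5159 ± 698). Haemoglobin genes took 0.382 ± 0.294%, with 0.175% in replicate 1 and 0.590% in replicate 2.

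Orthologs of genes that mark the choroid plexus epithelium of mammals were abundant. Of 46 matched members of this list, 32 were detected, 23 were at a TPM of at least 10 and 15 at 100, and the list median exceeded the medians of all 10000 random lists. Besides rbp4, the insulin-like growth factor carrier igfbp2a was at 1917 ± 21.1 TPM, the chloride channel family gene clic6 at 1469.5 ± 61.9, the sodium pump subunits atp1b1a at 1234 ± 403 and atp1a1a.1 at 868 ± 268, the keratin krt8 at 838 ± 45.8, the growth factor igf2b at 741 ± 67.7 and the midkine mdkb at 684 ± 44.4. The transcription factor otx2b, required for choroid plexus development in mice, was at 302 ± 40.5 TPM. Several mammalian markers were low. The thyroid hormone carrier ttr was at 0.355 ± 0.219 TPM, from 1 and 3 expected counts, kl was at 0.205 ± 0.0071, kcnj13 at 2.33 ± 1.39, enpp2 at 3.00 ± 1.91 and trpv4 at 1.28 ± 0.537 TPM. The member rdh5 was at 61.2 and 2.56 TPM in replicates 1 and 2, a difference in the direction of the pineal genes, and was named after its values were seen. The list was made from mammalian genes, and 35 of its members are also on other lists.

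Genes of motile cilia were transcribed broadly. Of 91 matched axoneme and assembly genes, 85 were detected and 74 were at a TPM of at least 10, with enkur at 165 ± 13.6, spag8 at 135 ± 60.5, ak7a at 132 ± 3.07 and meig1 at 109.6 ± 19.9 TPM. Of 25 intraflagellar transport genes, 24 were detected and 20 were at 10 or above, with ift74 at 43.1 ± 8.08, ift88 at 38.1 ± 12.9, ift172 at 38.1 ± 4.77 and ift46 at 37.0 ± 1.99 TPM. Median levels stood above all random lists for the axoneme and at the 99.97 percentile for intraflagellar transport. Among transcription factors of the multiciliated program, 9 of 11 were detected and 5 were at 10 or above. The regulators of motile ciliogenesis foxj1b and foxj1a were at 80.0 ± 14.6 and 41.8 ± 2.09 TPM, rfx2 at 36.5 ± 9.45, rfx3 at 11.8 ± 5.81, gmnc at 28.8 ± 17.6, e2f5 at 18.9 ± 3.27, e2f4 at 7.24 ± 0.0071 and foxn4 at 3.02 ± 0.827, and the list median lay at the 95.3 percentile.

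Junction genes were led by ctnnb1 and cdh2. Of 64 matched members, 37 were detected and 23 were at 10 or above. The catenin genes ctnnb1, ctnnd1 and ctnna1 were at 226 ± 18.0, 67.8 ± 6.65 and 61.1 ± 11.4 TPM, the cadherin cdh2 at 204 ± 7.31, crb2b at 65.0 ± 22.8, nectin1b at 41.3 ± 19.1 and tjp2b at 40.5 ± 3.57 TPM. The claudin cldn19, among the 8 highest members, was at 45.7 ± 17.9 TPM. Of the claudins in the fixed set, cldn5a was at 37.9 ± 4.77 and cldn2 at 1.42 ± 1.14 TPM. The list median lay at the 59.2 percentile.

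Ion transport rested on few genes at high levels. Of 119 matched members, 61 were detected, 32 were at 10 or above and 9 at 100 or above, and the list median lay at the 35.13 percentile. The sodium pump gene atp1a1b was at 1059.6 ± 0.276 TPM, its regulator fxyd1 at 612 ± 169, the carbonic anhydrase ca5a at 579.9 ± 61.7, the anion exchanger slc4a2b at 547 ± 190.2 and the bicarbonate cotransporter slc4a7 at 234 ± 70.0 TPM. The sodium, potassium and chloride cotransporter slc12a2 was at 73.3 ± 3.63 and the water channel aqp1a.1 at 14.0 ± 1.38 TPM.

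Nutrient, hormone and xenobiotic transporters were detected for 97 of 132 matched members, 62 of them at 10 or above and 17 at 100 or above, and their median exceeded that of all random lists. The amino acid transporter slc7a8b was at 1033 ± 284 TPM, its partner chain slc3a2b at 567 ± 52.7, the glutamine transporter slc38a3a at 425 ± 59.4, slc16a9a at 769 ± 47.9 and the retinol receptor stra6 at 721 ± 41.7 TPM. The lipoprotein receptor lrp1aa was at 439 ± 0.283, and the fatty acid binding protein genes fabp7a and fabp11a were at 803 ± 164 and 423 ± 144 TPM.

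Of 124 matched secreted proteins, growth factors and carriers, 66 were detected and 16 were at 100 or above, and the median lay at the 40.7 percentile. Of 59 complement and innate defence genes, 27 were detected, with b2m at 556 ± 7.48, masp1 at 202 ± 40.6, c3b.1 at 194 ± 126 and mhc1zba at 99.8 ± 19.8 TPM, and the median lay at the 11.4 percentile. Of 106 signalling receptors, 74 were detected, with the adrenergic receptor adrb1 at 154 ± 42.8, the Wnt receptor fzd7a at 129 ± 15.6, the insulin receptor insrb at 97.7 ± 2.40 and erbb4a at 79.8 ± 25.2 TPM, at the 99.5 percentile. Of 70 transcription factors of the roof plate and dorsal midline, 40 were detected and 12 were at 100 or above, with id2a at 336 ± 14.9, id1 at 287 ± 44.1 and barhl2 at 218 ± 4.50 TPM, and the median lay at the 57.9 percentile.

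**Figure D2:**
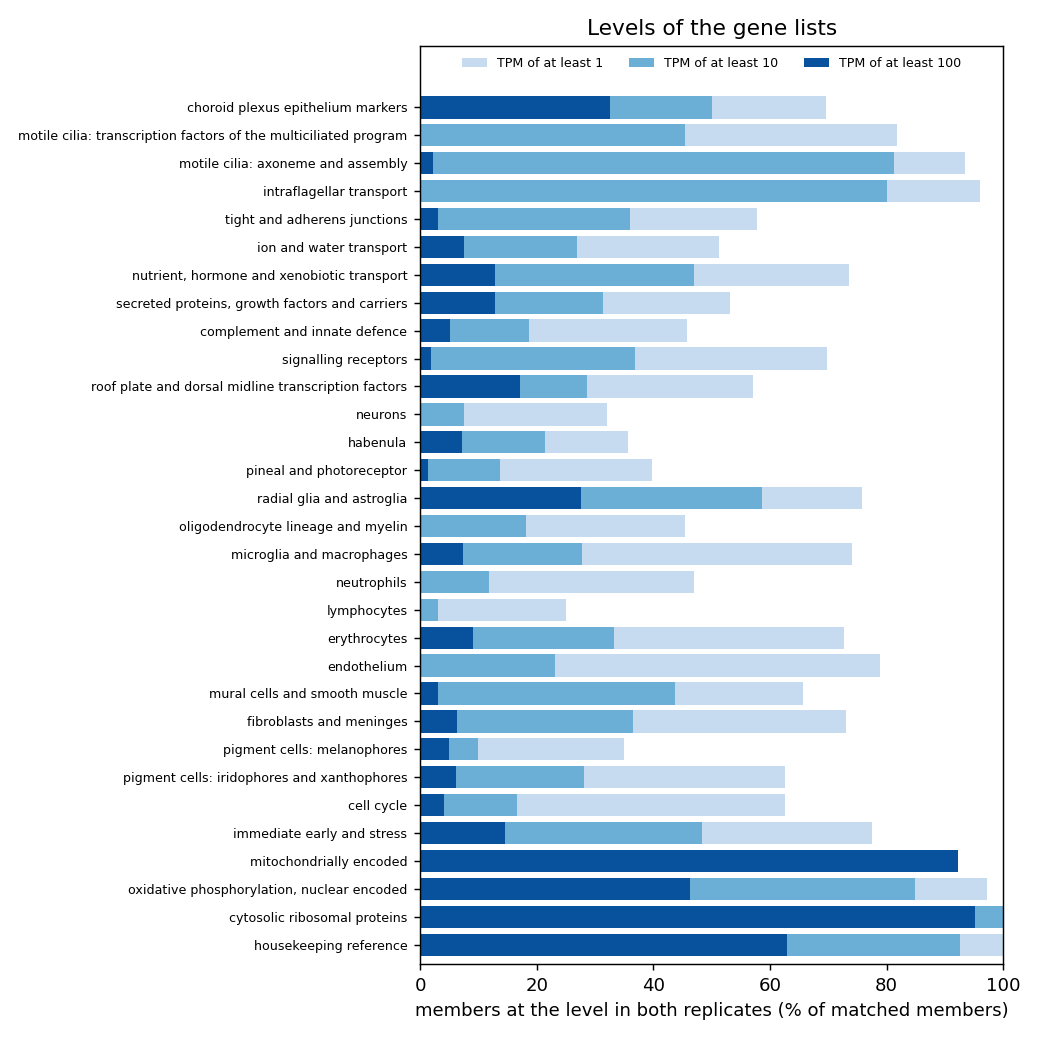
Bars give, for each of 31 gene lists (y axis), the share of matched members at a TPM of at least 1, 10 or 100 in both replicates (x axis, percent). The axoneme list has 85 of 91 members at a TPM of at least 1, and the neuron list 17 of 53.

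Markers of other cell types were also present. These lists share members with other lists, namely 8 of 29 radial glia, 12 of 63 fibroblast and 14 of 54 microglia and macrophage genes. Levels of shared genes do not by themselves point to a cell type. Of 29 radial glia and astroglia genes, 22 were detected, with glulb at 1036 ± 139.7 and glula at 953 ± 67.4 TPM, and the median exceeded all random lists. The astroglial filament gene gfap was at 3.65 ± 0.728 TPM. Of 63 fibroblast and meninges genes, 46 were detected, with slc13a3 at 419 ± 105, mmp2 at 157 ± 3.72, rdh10a at 139.9 ± 49.1 and loxl1 at 127 ± 28.9 TPM, at the 99.0 percentile. Of 52 endothelial genes, 41 were detected, with plvapa and plvapb, which encode the diaphragm protein of fenestrated endothelium, at 74.4 ± 3.56 and 24.6 ± 2.5, cav1 at 41.1 ± 7.38, podxl at 32.7 ± 1.97 and kdrl at 32.0 ± 2.25 TPM, at the 69.2 percentile. Of 32 mural and smooth muscle genes, 21 were detected, with myl9a at 142 ± 2.04, epas1a at 79.5 ± 4.84, pdgfrb at 66.3 ± 2.35 and myl9b at 50.6 ± 18.5 TPM, at the 80.4 percentile.

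Among immune and blood lists, 40 of 54 microglia and macrophage genes were detected, with lgals3a at 189.8 ± 10.8, cd74a at 165 ± 45.1, lgmn at 127 ± 7.47 and apoeb at 116 ± 76.3 TPM, at the 96.3 percentile. The macrophage gene mpeg1.1 was at 2.74 ± 0.608 TPM. Of 17 neutrophil genes 8 were detected, led by srgn (49.2 ± 4.48) and nccrp1 (32.4 ± 0.191), at the 30.8 percentile. Of 32 lymphocyte genes 8 were detected, led by sla2 (14.8 ± 4.28) and cxcr4b (9.60 ± 0.339), at the 3.22 percentile. Of 33 erythrocyte genes 24 were detected, at the 76.8 percentile. They were led by the globins hbba1 (1322 and 4496 TPM in replicates 1 and 2) and hbaa1 (353 and 1319 TPM). The hbba1 values are sums over gene entries of that symbol, and the entry that differed 4-fold stood at 951 and 3299 TPM. The genes prdx2 and tmod4 were at 345 ± 47.0 and 64.4 ± 12.7 TPM.

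Neuronal and other brain lists were lower. Of 53 neuron genes 17 were detected in both replicates, led by stmn1b (70.6 ± 24.1), the serotonin transporter slc6a4a (60.9 ± 4.26), map2 (30.6 ± 1.70) and camk2b1 (24.1 ± 7.72), at the 6.54 percentile. In replicate 1 alone 33 neuron genes were at a TPM of at least 1. The neuronal RNA binding protein gene elavl3 was at 0.755 ± 0.417 TPM. Of 14 habenula genes 5 were detected, led by kctd12.1 (127 ± 2.32) and nrp1a (76.9 ± 24.3), at the 1.41 percentile. Of 22 oligodendrocyte and myelin genes 10 were detected, led by aspa (150.5 ± 85.2), with mbpa at 5.75 ± 1.01 TPM, at the 14.9 percentile. Of 73 pineal and photoreceptor genes 29 were detected in both replicates and 54 in replicate 1 alone, and the list median lay at the 99.93 percentile in replicate 1 and at the 2.47 percentile in replicate 2.

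Of 20 melanophore genes 7 were detected, led by pmelb (146 ± 32.3) and slc24a5 (14.9 ± 1.90), at the 18.2 percentile, and mitfa, which nacre fish lack in functional form, was at 0.81 ± 0.877 TPM. Of 32 iridophore and xanthophore genes 20 were detected, led by mdh1aa (1437 ± 18.0) and rpe65a (411 ± 111), at the 87.1 percentile. Of 48 cell cycle genes 30 were detected, with hmgb2a at 266 ± 27.7, hmgb2b at 162 ± 22.9, pcna at 83.0 ± 15.7 and tubb2b at 61.6 ± 9.48 TPM, at the 40.2 percentile. Of 62 immediate early and stress genes 48 were detected, with fkbp5 at 1936 ± 16.3, hspa8 at 858 ± 128, hspb1 at 425 ± 158 and btg1 at 365 ± 127 TPM, at the 99.99 percentile. Mitochondrially encoded genes were detected for 12 of 13, nuclear genes of oxidative phosphorylation for 103 of 106 (atp5mc3b at 1071 ± 241, atp5l at 941 ± 17.4, atp5fa1 at 767 ± 49.97, atp5f1b at 755 ± 26.3), ribosomal proteins for 82 of 82 and housekeeping genes for 27 of 27 (rplp0 at 4006 ± 1041). The medians of these 4 lists exceeded all random lists.

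Between the replicates, pineal and photoreceptor genes stood out. Their median was 5.23-fold higher in replicate 1 (log2 -2.39, replicate 2 over replicate 1), and 42 of 54 members with a mean TPM of at least 1 were at least 2-fold higher there. The size of the shift depended on the pseudocount and the filter, with a median log2 ratio of -3.95 on the TPM + 0.1 scale and -3.24 at a mean TPM of at least 5. The pineal opsin gene exorh was at 656 and 11.7 TPM in replicates 1 and 2, the phototransduction genes pde6ha at 812 and 13.0, gnat1 at 152 and 1.68 and gngt1 at 351 and 2.2, and aanat2, which encodes an enzyme of melatonin synthesis, at 14.4 and 0.83 TPM. Not all members moved. Of 25 members with a mean TPM of at least 10, 6 did not differ by the rule of 4-fold, namely arl3l2, rpe65a, gnb1a, gnb1b, unc119b and pde6c, and pde6c was higher in replicate 2 with 39.3 and 58.5 TPM. These 6 were named after their values were seen.

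Of the 31 lists, 4 were lower in replicate 2 than random lists of like abundance, 9 were higher and 18 were inside. Besides the pineal list, neuron genes were lower (median log2 -0.85), with 9 of 26 members at least 2-fold lower. The size depended on the setting, with a median of -0.81 with TMM scaling, -1.14 with CPM and -1.43 on the TPM + 0.1 scale. Junction genes (-0.23) and immediate early and stress genes (-0.13) were lower by little, and both came inside the central 95% with CPM. Higher in replicate 2 were mitochondrially encoded genes (0.74), ribosomal proteins (0.48), microglia and macrophages (0.44), housekeeping genes (0.41), mural cells (0.36), erythrocytes (0.33), iridophores and xanthophores (0.28), oxidative phosphorylation (0.28) and endothelium (0.24). All 84 ribosomal protein genes and all 12 mitochondrially encoded genes compared were higher in replicate 2, and 41 of 45 microglia and macrophage genes were. For the most abundant lists, random lists of like abundance also lay above 0. Their central 95% ran from 0.196 to 0.384 for ribosomal proteins and from 0.0637 to 0.261 for oxidative phosphorylation. It ran from 0.0059 to 0.363 for housekeeping and from 0.000303 to 0.491 for mitochondrially encoded genes. Part of these ratios is therefore shared with other abundant genes. The oxidative phosphorylation list came inside when random lists were matched on length too, and it and the iridophore and xanthophore list did so with a mean TPM of at least 5. The axoneme list (0.02), intraflagellar transport list (-0.06) and choroid plexus epithelium list (0.28) were inside. Of the 18 lists inside, 6 came outside in at least 1 alternative. The fibroblast and meninges list (0.14) was higher at a mean TPM of at least 5, with CPM, with members of more than 1 list left out and with length matching. The choroid plexus epithelium list was higher with length matching, the secreted protein and complement lists with CPM, and the melanophore list with TPM + 0.1 and with length matching, while ion and water transport was lower with members of more than 1 list left out.

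**Figure D3:**
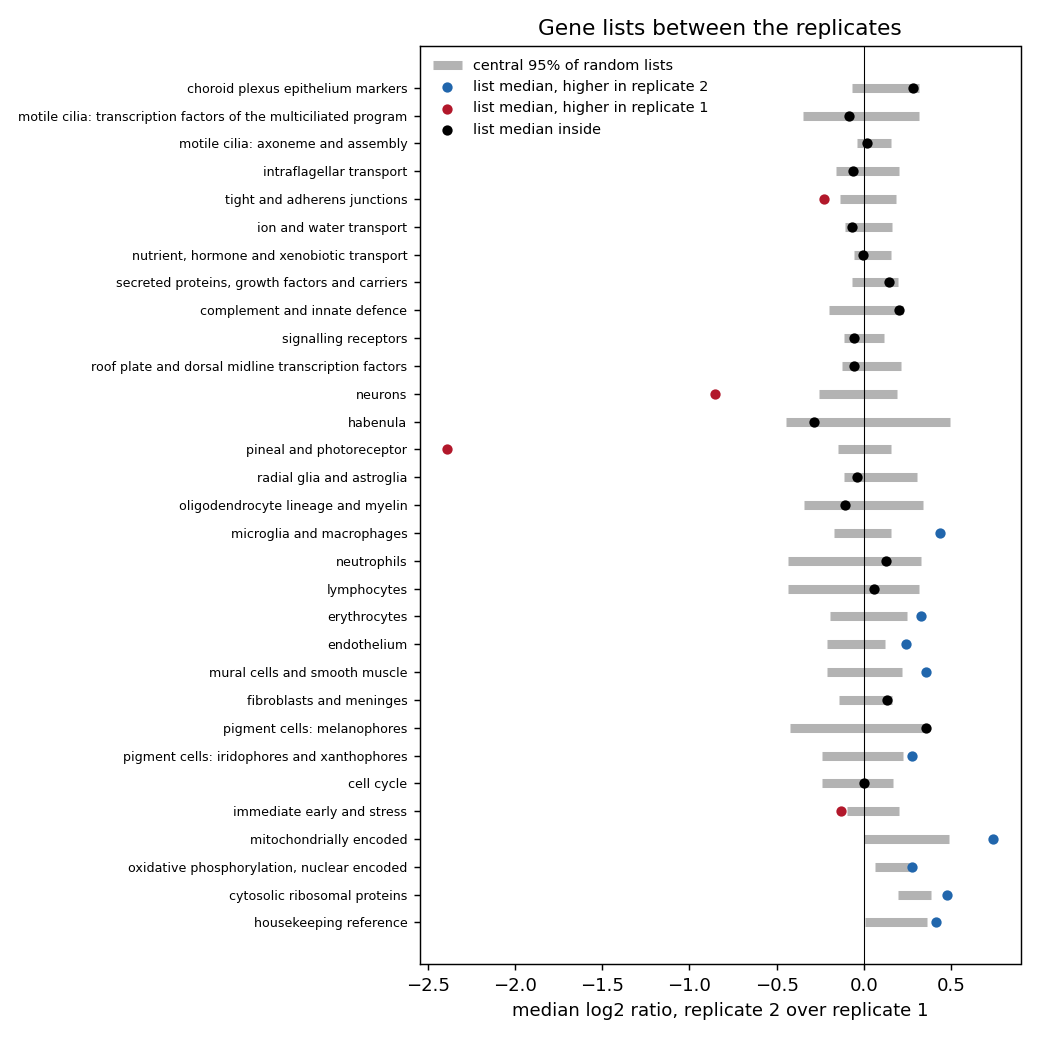
Points give the median log2 ratio of each of 31 gene lists (y axis), replicate 2 over replicate 1 (x axis), less the median of all genes, and grey bars the central 95% of random lists matched on mean TPM. Red points lie below the bars and blue points above, with the pineal and photoreceptor list at -2.39 and the mitochondrially encoded list at 0.74.

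Of 7492 genes with a mean TPM of at least 10, 107 (1.43%) differed at least 4-fold between the replicates, 67 higher in replicate 1 and 40 higher in replicate 2. Of the 67, 19 are on the pineal and photoreceptor list, and none of the 40. Among the largest ratios toward replicate 1 were those of rcvrnb (862 and 5.50 TPM), gngt1, si:ch211-245j22.3 (129 and 0.43), rcvrn3 (120.4 and 1.05), pde6ha, gnat1, exorh, zgc:174353 (46.3 and 0) and si:zfos-2326c3.2 (213 and 4.47). The rcvrn genes encode recoverins, calcium sensors of photoreceptors. For si:zfos-2326c3.2 the expected counts were 326 and 341, so the TPM ratio came from the effective length, and with CPM its log2 ratio was 0.02. It was not the only gene with a TPM ratio well beyond that of its counts, and such genes were not tallied. Examples chosen after their values were seen are nmnat3 (134 and 88 expected counts, 11.1-fold by TPM) and arhgap32a (678 and 499, 5.53-fold). Toward replicate 2, bckdhb had 592 and 834 expected counts at 7.02-fold, and prkn 42 and 56 at 4.18-fold.

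Toward replicate 2 the largest ratios were those of CT027801.1 (0 and 246 TPM, from 0 and 2.97 expected counts), mhc1uba (0 and 122), si:dkey-11o1.6 (0.4 and 99.9), nme2b.2 (2.65 and 102), actc1b (3.3 and 113), slc38a11 (1.96 and 74.0), pvalb3 (1.05 and 30.6), vtg1 (1.15 and 31.1), pvalb4 (1.74 and 38.62) and pvalb2 (2.25 and 45.5). The pvalb genes encode parvalbumins, abundant in fast muscle, actc1b a muscle actin, vtg1 the yolk precursor vitellogenin, and mhc1uba a class I histocompatibility protein. Of the 107 genes, 6 had under 50 expected counts in both replicates and 8 had transcripts under 500 bases. Each replicate is a single library, so these ratios have no replicate check, and reads shared between close copies, such as the globin genes, were divided by RSEM's estimate.

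Copies of duplicated genes were often used unequally. Of 239 pairs of genes with symbols ending in a and b, 135 had a copy at a mean TPM of at least 10, and 65 of these were unequal, 36 with the a copy higher and 29 with the b copy higher. Among the unequal pairs, the log2 ratio of a over b was -11.75 ± 0.26 (SD, n = 2) for dkk3, 3.51 ± 0.53 for igfbp2, 8.86 ± 0.36 for atp1b1, -2.83 ± 0.15 for atp5mc3, 7.57 ± 0.44 for slc16a9, -6.24 ± 0.39 for igf2, -4.24 ± 0.62 for slc3a2, -6.83 ± 0.46 for slc4a2 and 4.66 ± 0.32 for lrp1a. Thus igf2b was at 741 ± 67.7 TPM beside igf2a at 8.88 ± 1.79, and atp1b1a at 1234 ± 403 beside atp1b1b at 1.58 ± 0.205. In 47 pairs both copies were at a TPM of at least 10 in both replicates. Symbols alone defined the pairs. A list made by hand marked 11 of the 239 as different subunits or family members, 1 of them among the unequal pairs. Other pairs that are not duplicated copies may remain, such as tfap2a and tfap2b.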

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

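No paired analysis was possible because there is 1 group. Of 259 alternative values of the counts and shares that answer a comparison, 241 stayed within 1.5 times or 1 spread and 18 did not. The main r of 0.957 became 0.924 with log2(TPM + 0.1), 0.966 without a filter, 0.933 at a mean TPM of at least 1, 0.965 with CPM and 0.954 without mitochondrial, ribosomal and haemoglobin genes, all beyond its 95% interval over genes. The share of the 10 most abundant genes was 21.7% both with CPM and without mitochondrially encoded genes, and 13 of the 20 most abundant genes stayed with CPM. A TPM of at least 2 left 18 pineal and photoreceptor, 5 neutrophil, 4 lymphocyte and 3 melanophore genes detected, and 13 lymphocyte genes passed 0.5, as a threshold moves such counts by construction. Leaving out a replicate gave 17 to 33 neuron genes and 29 to 54 pineal and photoreceptor genes, the higher count being replicate 1 alone. Genes differing between replicates numbered 183 at a mean TPM of at least 5 and 62 at 20, since more or fewer genes were compared, and unequal pairs numbered 98 at 2-fold. The ratio of si:zfos-2326c3.2 turned from below 0 to 0.0243 (log2) with CPM. Of the 31 lists between replicates, 21 kept their position in every setting, 9 of them outside, and 10 changed it in at least 1. Over all 1212 alternative values, single genes and percentiles included, 1085 stayed, 126 moved and 1 turned. Part of those that stayed could not have moved. For levels of single genes and the share of the 10 most abundant genes, leaving out a replicate always keeps the value within 1 SD. The SD of 2 values is never below the distance of each from their mean. TMM scaling shifts all ratios alike, so it cannot change the percentile of a list between replicates. Alternatives chosen after seeing the data were unmatched symbols at 0, thinning for the lists, matching on length and those for single genes. Leaving out pineal genes, short transcripts, genes under 50 counts or pairs of different subunits or family members was also chosen then. Counts of the series table were not run, because that table holds mean TPM, and ratios between replicates have no value with a replicate left out. The cause of the other moves was not tested.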

Other observations

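The set of genes below was put together after its values were seen, and included genes that handle steroids and retinoids. Several were already part of the comparisons above. The genes tph1a, tph2 and rbp2a were among those that differed between replicates, and crabp2a was the higher copy of an unequal pair. The glucocorticoid-inactivating enzyme gene hsd11b2 was at 1910.5 ± 384 TPM (SD, n = 2), near the level of fkbp5, a glucocorticoid-induced gene, at 1936 ± 16.3 TPM. The cellular retinoic acid binding protein gene crabp2a was at 72.6 and 137 TPM in replicates 1 and 2 and rbp2a at 8.26 and 58.5. The serotonin synthesis genes tph2 and tph1a were at 39.9 and 0.2 and at 52.2 and 0.42 TPM, while the transporter slc6a4a was at 57.8 and 63.9. The globin genes hbaa2 and hbba2 were at 28.6 and 29.6 and 44.2 and 52.3 TPM, near equal where hbaa1 was not.

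No biological explanation was tested for the patterns below, because the design has 1 group. The tests on shared opsin reads, on other brain tissue and on the oxidative phosphorylation list, and the other filters of the muscle list, were chosen only after the results were seen, and the junction list took the place of the axoneme list, for which a test was written but which turned out to lie inside the central 95% (percentile 17.6).

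Pineal and photoreceptor genes were higher in replicate 1, although the gland was dissected away. Reads shared among opsins do not account for the whole of it, since the 23 members other than opsins with a mean TPM of at least 10 had a median log2 ratio of -4.09. Other brain tissue in the replicate 1 pool stays open. Its prediction needed medians at least 2-fold lower in replicate 2 for neuron genes and for habenula and oligodendrocyte genes. Neuron genes had a median of -0.85, which passed that bound only with CPM (-1.14) and on the TPM + 0.1 scale (-1.43). The 9 habenula and oligodendrocyte genes at a mean TPM of 1 to 10, near the floor, had a median of -0.05. Pineal tissue left in the replicate 1 pool is a candidate explanation. The 28 members at a mean TPM of 1 to 10 had a median of -1.997 (quartiles -2.62 and -1.09). However, they belong to the list that shows the shift and do not tell its source. The members rpe65a, gnb1a, gnb1b, pde6c and unc119b stayed within 2-fold. All but unc119b were at 58.5 to 333 TPM in replicate 2, where a small addition changes the ratio little. That reasoning holds less for unc119b, at 23.0 and 20.1 TPM in replicates 1 and 2. Of the 28 members at 1 to 10 TPM, 21 were at least 2-fold lower in replicate 2. Among those that were not are impg1b (4.89 and 5.75 TPM) and unc119a (5.03 and 4.33 TPM). The members that stayed do not decide the question. Strain, purification, batch and biological variation between the pools stay open.

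Skeletal muscle genes were higher in replicate 2. Of a muscle list of 52 genes written afterwards, 43 matched with the genes already seen left out (the parvalbumins, actc1b and nme2b.2), and the 20 with at least 10 expected counts in either replicate had a median log2 ratio of 1.19 (quartiles 0.54 and 2.24). The size depends on that filter, as the 10 with such counts in replicate 1 had a median of 0.98 and the 39 with any reads 0.63, with 35 of the 39 higher in replicate 2. Counting error does not account for it: the summed counts of the 20, 1014 and 2833, gave a ratio of 2.43 with a 95% interval from 2.26 to 2.62 (exact binomial, counting error only), and 3.196 without eno3. The median reached the 2-fold set beforehand under the filter for which that bound was written. It did not under the 2 other filters, which were added afterwards. Muscle RNA in the replicate 2 pool stays open, since genes could pass the first filter through replicate 2 alone, and mybpc1 and mylpfb were lower in replicate 2.

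Longer transcripts were lower in replicate 2, with a Spearman correlation across 7492 genes of -0.18 between length and the log2 TPM ratio, where genes are not independent replicates. The trend did not come from the effective lengths behind TPM, as the correlation with CPM was -0.17. Matching random lists on length left the junction list low (percentile 0.27) and the ribosomal proteins high (percentile 100), so length alone does not explain these, within the coarse bins of the most abundant genes. The oxidative phosphorylation list came inside (percentile 86.9), so its position may follow length, or the wider bins of mean TPM used in that setting. RNA integrity, purification, library preparation and other differences between the batches stay open. Length less effective length, which follows fragment size, had medians of 263 and 272 bases in replicates 1 and 2. Mitochondrially encoded genes took 8.02% and 11.1% of TPM and ribosomal proteins 20.2% and 24.0%. These values do not tell the explanations apart.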
